A study of Mus musculus with 7 samples.

How the data were processed

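Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on liver and kidney of C57BL/6 mice. In liver, taken at Zeitgeber time (hours after lights on) 7, there were 2 BMAL1 libraries and 1 PROX1 library. In kidney, taken at Zeitgeber time 8, there were 2 BMAL1 libraries and 2 HNF1B libraries. PROX1 and HNF1B are called cofactors here as a short name only, and whether they act with BMAL1 was not tested. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate animals.

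The authors deposited 1 list of peaks per library. Per the submitters' processing notes, Bowtie2 2.5, bedtools 2.31 and HOMER 4.11 were used and the genome build was GRCm39. Per the file headers, peaks were called by HOMER on each library separately, and the recorded command named no control library. The headers give a peak size of 150 bp, a minimum distance of 300 bp between peaks and a false discovery rate of 0.001. They also give a fold of 4 and a p-value of 0.0001 against the local 10000 bp, and at most 2 tags counted per position. Because no input library entered the calls, a peak can hold signal that any antibody would give, and the minimum distance allows a wide site to be listed at slightly different centres in different libraries. Total tags per library ran from 41878462 to 46693500, per the file headers, and 12.3 to 18.4% of tags lay in peaks.

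The deposited score column held the value 1 on every line, so the score could not rank peaks. The order of the lines was used in its place and is called listing position here. The use of this order was checked on the files: 95.3 to 98.4% of the first 5000 peaks of a replicated library overlapped a peak of the other replicate, against 18.6 to 49.9% of the last 5000. Listing position was used to describe and filter peaks within a list, to form strata of BMAL1 regions, to compare the peaks listed first between libraries, and for rank correlations between libraries over their common regions. It is a rank and not a measure of signal, and the lists differ in length. The lists hold no read depth per peak, so intervals and p-values measure counting error over regions only. Neighbouring regions are not independent, and the spread between replicates may be technical.

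Peaks of the 7 libraries that overlapped by at least 1 bp were merged into regions. A region was called reproducible in a group where every library of the group had a peak, which for PROX1 is 1 library. Reproducible BMAL1 regions were called shared where both libraries of both tissues had a peak, and liver-only or kidney-only where both libraries of that tissue and neither library of the other tissue had a peak. Regions with a BMAL1 peak in 1 library of the other tissue stayed outside these 3 classes. Shares carry 95% Wilson intervals. Contrasts were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 5 tests, and p-values too small for a computer's number range are given as log10 p. Standard errors of log2 odds ratios came from a jackknife that left out 20 chromosomes in turn. For log2 odds ratios pooled over strata of listing position, they came from the Mantel-Haenszel estimate, which treats regions as independent. Overlap expected by position alone came from 100 shuffles of peaks within chromosomes. The Jaccard index, which is the number of regions common to 2 lists divided by the number in either, was computed over whole lists and over the peaks listed first. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. The odds ratio code was tested on simulated data for the HNF1B comparison (56847 sites), where a planted log2 odds ratio of 5.47 was recovered as 5.59, and the overlap code on 39678 simulated peaks, where a planted overlap of 60% was recovered as 60%.

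The groups, the 3 BMAL1 classes, the main tests and a first set of alternatives were fixed before the data were examined. The alternatives were peak centres within 100 bp, a stricter peak threshold, autosomes, either replicate in place of both, exclusion of regions present in all 7 libraries, each replicate left out and a replicate block. Added after the data were seen were centres within 500 bp, the first 10000 and first 60000 listed peaks, exclusion of chromosome Y and unplaced sequences, strata of listing position, exclusion of regions present in all 7 libraries for the cofactor contrasts, and all comparisons by listing position or by distance between peak centres.

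No sequence or gene annotation of the build of the files was used here, and coordinates were not converted between builds. Motif shares, genomic annotation, distance to promoters and gene lists, all planned, were therefore not analysed here, and regions are named by position without a gene. The planned rule for named genes was replaced, after the files were seen, by the 8 regions of each class with the lowest mean listing position over the libraries that define the class, from which the text takes examples. Classes of regions named by this rule include the 3 BMAL1 classes, tissue-only regions with the cofactor, tissue-only regions over 5 kb from a BMAL1 peak of the other tissue, BMAL1 regions of all 4 libraries without a cofactor, and regions of 1 cofactor alone.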

Results

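The data comprised 7 peak lists that map where 3 transcription factors bound chromatin in mouse liver and kidney. BMAL1 is a core circadian clock protein that binds DNA together with CLOCK. PROX1 and HNF1B are homeodomain proteins, with roles in liver and in kidney and liver, respectively. The liver lists held 61808 and 76136 BMAL1 peaks (replicates 1 and 2) and 61204 PROX1 peaks. The kidney lists held 76166 and 78522 BMAL1 peaks and 77405 and 80251 HNF1B peaks. Per the file headers, similar numbers of tags, 41878462 to 46693500 per library, lay behind these lists. Merging all lists gave 167919 regions on GRCm39. Tissue went together with collection time (Zeitgeber time 7 in liver, 8 in kidney), so every difference between tissues is also a difference between those samplings.

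Within each group, most binding sites were found in both replicates. In liver, 72.2% of BMAL1 peaks (95% Wilson interval 72.0 to 72.4%, n = 137944 peaks in 2 libraries) overlapped a peak of the other replicate. In kidney, the share was 79.2% for BMAL1 (79.0 to 79.4%, n = 154688) and 81.3% for HNF1B (81.2 to 81.5%, n = 157656). Peaks of a replicate moved to random places on their chromosome overlapped the other replicate in at most 1.05% of cases in 100 shuffles. Lists of another antibody in the same tissue came near the replicate shares. A PROX1 peak was overlapped by 72.0 and 60.9% of liver BMAL1 peaks (replicates 1 and 2). An HNF1B peak was overlapped by 69.9 to 72.1% of kidney BMAL1 peaks. PROX1 had 1 library and no replicate check.

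The first comparison asked how far BMAL1 occupied the same sites in liver and kidney. BMAL1 was reproducible at 50726 regions in liver and 61839 in kidney, and 24875 regions were shared. The shared regions made up 49.0% of the liver regions (95% Wilson interval 48.6 to 49.5%) and 40.2% of the kidney regions (39.8 to 40.6%). Most of them, however, were among the regions with a peak in all 7 libraries: without those, 5952 shared regions made up 18.7% of the liver and 13.9% of the kidney regions. A further 21685 regions were liver-only and 30127 were kidney-only, while 4166 liver regions had a peak in 1 kidney BMAL1 library and 6837 kidney regions had a peak in 1 liver BMAL1 library.

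Examples of the classes lay far forward in the lists. A shared region on chromosome 9, 44792649 to 44792804, was listed at positions 4 and 6 in liver BMAL1 and at 7 and 5 in kidney BMAL1. The same region stood at position 294 for PROX1 and at 2188 and 2193 for HNF1B. It was an exception, since the others of the 8 shared regions listed first stood at position 12 or earlier in all 7 lists. Liver-only regions more than 5 kb from any kidney BMAL1 peak numbered 11008, or 50.8% of that class. Among them, chromosome 7, 49001643 to 49001932, was listed at 203 and 81 in liver BMAL1, with the nearest kidney BMAL1 peak 9818 bp away. Chromosome 7, 65452677 to 65452838, was listed at 1072 and 382, with the nearest kidney peak 65272 bp away. Kidney-only regions that far from a liver BMAL1 peak numbered 17975, or 59.7% of the class. Chromosome 18, 12139749 to 12139938, was listed at 93 and 111 in kidney BMAL1, 17828 bp from the nearest liver BMAL1 peak. Chromosome 18, 81134652 to 81134831, was listed at 142 and 191, and its nearest liver BMAL1 peak was 37366 bp away.

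Over all merged regions, reproducible BMAL1 binding in liver and in kidney co-occurred with a log2 odds ratio of 1.06 ± 0.036 (jackknife SE; log10 p = -996, adjusted -996, Fisher's exact test). The background is made of the peaks of these same libraries, and this value did not keep its direction under other settings. It was -1.23 when a peak in either replicate sufficed, so that fewer regions counted as lacking BMAL1 in both tissues. It was -1.001 without the 18923 regions that had a peak in all 7 libraries, an exclusion that removes only co-occurring regions. It lay between 0.31 and 0.60 when any 1 of the 4 BMAL1 libraries was left out, and was 1.91 for the first 10000 peaks of each list. Of liver BMAL1 peaks, 42.3 to 45.7% overlapped a kidney BMAL1 peak (4 library pairs), against at most 1.04% after shuffling. An HNF1B peak of kidney was overlapped by 39.7 to 42.3% of liver BMAL1 peaks (4 library pairs). Over whole lists, the overlap across tissues was therefore nearly as large with another antibody. Without liver BMAL1 replicate 1, the number of liver-only regions rose to 39373.

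The next comparison asked whether PROX1 went with BMAL1 sites of liver. PROX1 peaks were present at 77.0% of liver-only BMAL1 regions (95% Wilson interval 76.4 to 77.5%, n = 21685) and at 3.30% of kidney-only regions (3.11 to 3.51%, n = 30127). PROX1 was most frequent at shared regions, at 87.3% (86.9 to 87.7%, n = 24875). Liver-only regions with PROX1 included chromosome 8, 121274418 to 121274591, listed at 488 and 481 in liver BMAL1 and at 145 in PROX1. Chromosome 4, 57112235 to 57112417, was listed at 845 and 143 in liver BMAL1 and at 828 in PROX1, 9919 bp from the nearest kidney BMAL1 peak.

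The log2 odds ratio of a PROX1 peak at liver-only against kidney-only regions was 6.61 ± 0.063 (SE; log10 p = -7468), and against shared regions it was -1.04 ± 0.038 (log10 p = -187). Liver-only regions stood later in the BMAL1 lists than shared regions did: the foremost of 4 equal strata of listing position held 2861 liver-only and 8779 shared regions. In that stratum, PROX1 was present at 92.7% of liver-only and 92.3% of shared regions (log2 odds ratio 0.10, log10 p = -0.36), a difference that did not pass the test. In the stratum listed last, the shares were 56.4% and 69.4%. Over the 4 strata the common log2 odds ratio was -0.61 ± 0.039. Without the 18923 regions with a peak in all 7 libraries, which are all shared regions with PROX1, the log2 odds ratio against shared regions turned to 1.92, with PROX1 at 46.9% of the remaining shared regions. Kidney-only regions lack a liver BMAL1 peak by definition and PROX1 was measured in liver, so the contrast with them also compares regions with and without called BMAL1 binding in liver. Without liver BMAL1 replicate 1 the log2 odds ratios were 4.15 and -1.70, without replicate 2 they were 4.42 and -1.68, and PROX1 was then present at 52.1% and 64.0% of liver-only and at 5.76% and 7.69% of kidney-only regions, respectively.

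HNF1B was compared with kidney BMAL1 in the same way. HNF1B peaks of both replicates were present at 69.2% of kidney-only BMAL1 regions (95% Wilson interval 68.7 to 69.7%, n = 30127) and at 4.01% of liver-only regions (3.75 to 4.28%, n = 21685). HNF1B, like PROX1, was most frequent at shared regions, at 84.3% (83.8 to 84.7%, n = 24875). Kidney-only regions with HNF1B included chromosome 1, 35766540 to 35766704, listed at 188 and 238 in kidney BMAL1 and at 517 and 549 in HNF1B. Chromosome 1, 88163714 to 88163876, was listed at 1425 and 979 in kidney BMAL1 and further forward, at 364 and 224, in HNF1B, and lay 11414 bp from the nearest liver BMAL1 peak. By contrast, the kidney-only region on chromosome 18 at 12139749 stood only at 16359 and 12103 in the HNF1B lists.

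The log2 odds ratio of an HNF1B peak at kidney-only against liver-only regions was 5.75 ± 0.067 (SE; log10 p = -5636), and against shared regions it was -1.26 ± 0.048 (log10 p = -383). In the foremost stratum of listing position, HNF1B was present at 88.1% of kidney-only and 92.6% of shared regions, and in the last at 51.4% and 58.4%. The common log2 odds ratio over the 4 strata was -0.58 ± 0.034. Without the regions with a peak in all 7 libraries, the log2 odds ratio against shared regions (without strata) turned to 2.10, with HNF1B at 34.4% of the remaining shared regions. Liver-only regions lack a kidney BMAL1 peak by definition, as in the PROX1 comparison. With kidney BMAL1 replicate 2 left out, HNF1B was present at 7.56% of liver-only regions and the first log2 odds ratio was 4.02.

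**Figure D1:**
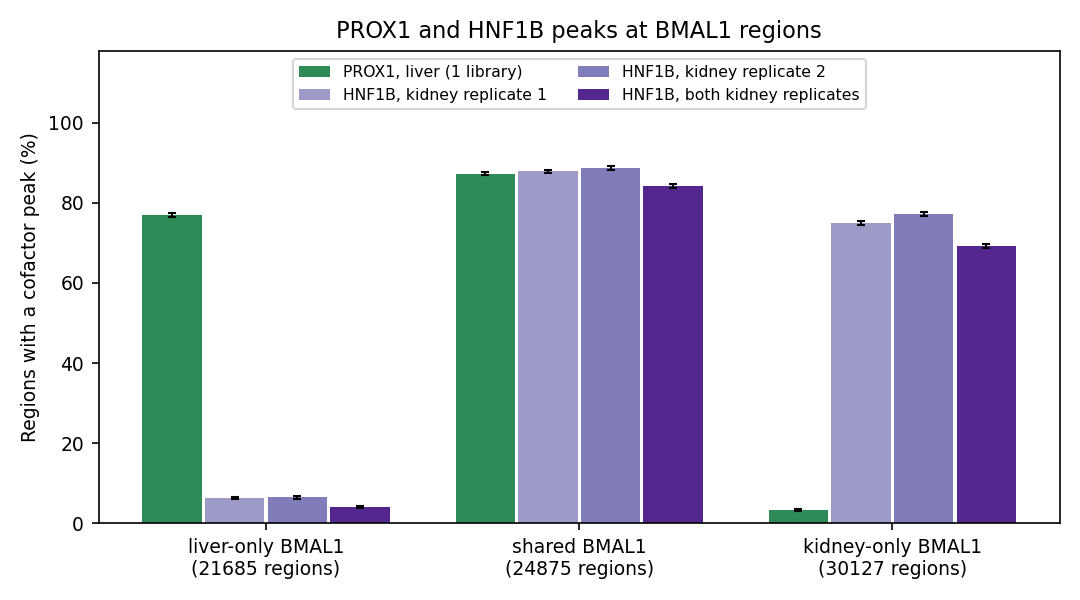
Percent of liver-only, shared and kidney-only BMAL1 regions with a PROX1 peak (liver) or an HNF1B peak (kidney, each replicate and both), with 95% Wilson intervals as error bars and the number of regions under each class. PROX1 reached 77.0% and 87.3% of liver-only and shared regions against 3.30% of kidney-only regions, and HNF1B of both replicates reached 69.2% and 84.3% of kidney-only and shared regions against 4.01% of liver-only regions.

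Whole BMAL1 lists resembled the cofactor of their tissue more than BMAL1 of the other tissue, whereas the BMAL1 peaks listed first resembled BMAL1 of the other tissue more. Over whole lists, the Jaccard index of liver BMAL1 with liver PROX1 was 0.535 to 0.589 and that of kidney BMAL1 with kidney HNF1B was 0.548 to 0.566. BMAL1 of liver with BMAL1 of kidney reached only 0.264 to 0.280. This was little above pairs of unlike antibodies across tissues. Those stood at 0.240 to 0.258 for liver BMAL1 with HNF1B, 0.248 to 0.255 for kidney BMAL1 with PROX1 and 0.240 to 0.246 for PROX1 with HNF1B. Among the first 1000 peaks, the order turned around: BMAL1 across tissues stood at 0.251 to 0.294 (4 library pairs), liver BMAL1 with PROX1 at 0.129 to 0.163 (2 pairs) and kidney BMAL1 with HNF1B at 0.0667 to 0.0817 (4 pairs). PROX1 of liver with HNF1B of kidney, which share neither antibody nor tissue, stood at 0.0995 to 0.101 (2 pairs), above kidney BMAL1 with HNF1B, and for the first 500 peaks at 0.135 to 0.139, above liver BMAL1 with PROX1 (0.1001 to 0.129). For the first 1000 peaks, the mean of BMAL1 across tissues exceeded that of BMAL1 with its cofactor by 0.126 ± 0.030 (SD) in liver and 0.199 ± 0.019 in kidney. The ranges of library pairs did not overlap. The SD is over library pairs that have libraries in common, so it is not a spread over independent replicates. Replicates of liver BMAL1 stood at 0.486, of kidney BMAL1 at 0.577 and of HNF1B at 0.736. With the first 5000 peaks the liver difference was already -0.0306, and with the first 20000 both differences were negative. The 2 liver BMAL1 libraries were not alike in this: among the first 10000 peaks, PROX1 stood at 0.502 with replicate 1 and 0.375 with replicate 2, and the replicates at 0.511 with each other. Replicate 1 stood at 0.611 with PROX1 and 0.595 with replicate 2 for the first 20000 peaks, but at 0.654 and 0.664 for the first 40000 and at 0.593 and 0.622 for the first 60000. Over whole lists, which differ in length, the values were 0.589 and 0.582.

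**Figure D2:**
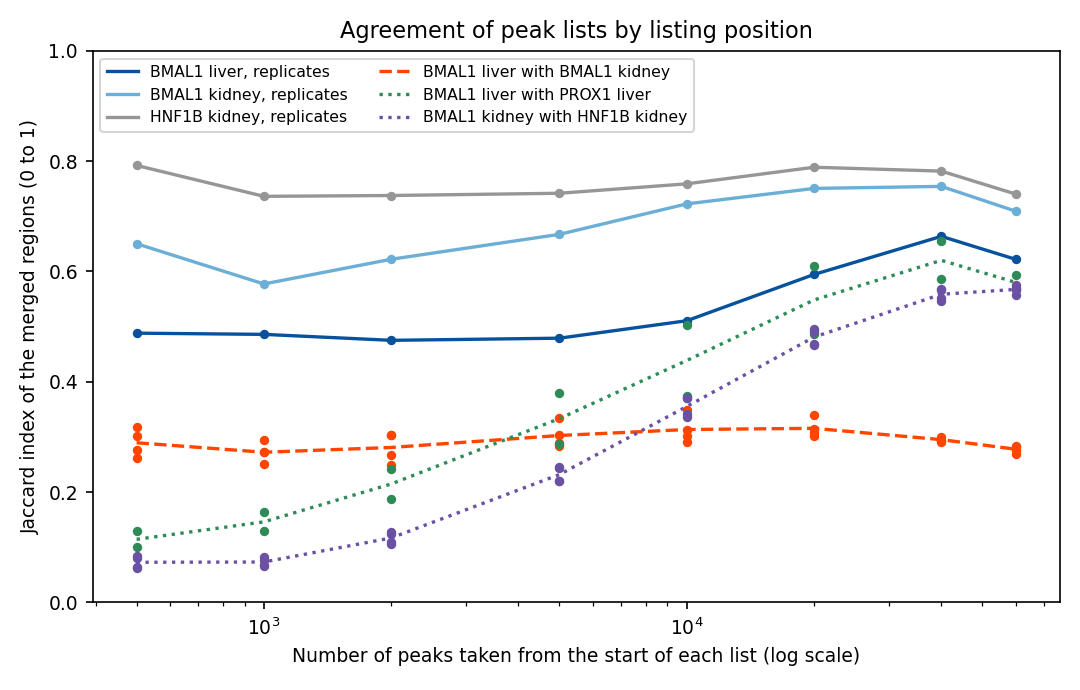
Jaccard index (0 to 1) of pairs of peak lists against the number of peaks taken from the start of each list (log scale), with points for library pairs and lines for the mean of each kind of pair. BMAL1 of liver with BMAL1 of kidney lay at 0.251 to 0.294 for the first 1000 peaks and at 0.269 to 0.284 for the first 60000, while BMAL1 with the cofactor of its tissue rose from at most 0.163 to at least 0.557.

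Most regions listed first for BMAL1 carried the cofactor as well, mostly at a later position. Of the 654 regions among the first 1000 peaks of both liver BMAL1 lists, 89.0% had a PROX1 peak (95% Wilson interval 86.4 to 91.2%) and 93.3% had BMAL1 peaks in both kidney libraries (91.1 to 94.95%). HNF1B, measured in the other tissue, had peaks in both kidney libraries at 85.9% of these regions (83.1 to 88.4%). Among the first 1000 peaks of the other lists were 297 of them for kidney BMAL1 (45.4%) and 183 for PROX1 (28.0%). Of the 732 such regions of kidney BMAL1, 92.5% had HNF1B peaks in both libraries (90.3 to 94.2%), and 100 (13.7%) were among the first 1000 of HNF1B. Regions listed first for a cofactor likewise carried BMAL1: 86.3% of the 1000 PROX1 regions (84.0 to 88.3%) had BMAL1 in both liver libraries, and 83.0% of the 848 HNF1B regions (80.3 to 85.4%) had it in both kidney libraries. Of the same PROX1 regions, 79.1% had HNF1B and 75.7% had BMAL1 in both kidney libraries. Of the same HNF1B regions, 75.2% had PROX1 and 61.1% had BMAL1 in both liver libraries.

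Peak centres showed the same turn by listing position. Around the first 1000 peaks of each kidney BMAL1 list, the median distance between centres within 500 bp was 4 bp to the other replicate, 10 to 14 bp to liver BMAL1 and 16 to 22 bp to HNF1B. Around the first 1000 liver BMAL1 peaks it was 6 bp to the other replicate, 9 to 11 bp to kidney BMAL1 and 13 to 17 bp to PROX1. At positions after 20000 and up to 40000 of the kidney lists, HNF1B centres lay 21 to 22 bp away and liver BMAL1 centres 24 to 34 bp away. In liver, this later turn was seen for replicate 1 (PROX1 22 bp, kidney BMAL1 34 to 35 bp) and not for replicate 2 (26 bp and 24 to 25 bp). These ranges are over library pairs and were not tested.

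**Figure D3:**
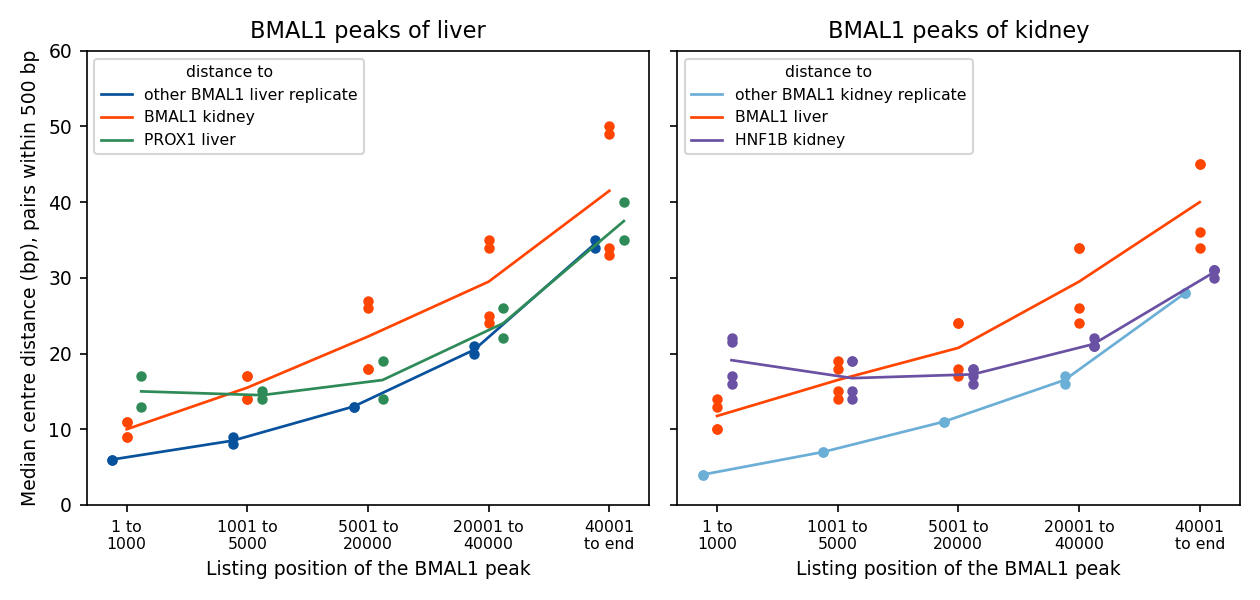
Median distance in bp between the centre of a BMAL1 peak and the nearest centre in another library, for pairs within 500 bp, by listing position of the BMAL1 peak in liver (left) and kidney (right). Points are library pairs and lines join their means; for the first 1000 kidney BMAL1 peaks, liver BMAL1 lay 10 to 14 bp and HNF1B 16 to 22 bp away.

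Some of the regions listed first in 1 tissue lay directly beside a BMAL1 peak of the other tissue. On chromosome 7, the liver-only region 45354474 to 45354650 (positions 60 and 44) and the kidney-only region 45354219 to 45354369 (46 and 58) were neighbours. The kidney peak centre lay 268 bp from the centre of the liver-only region, while the HNF1B peaks of kidney (3269 and 2564) lay at the liver position, as did PROX1 (231). On chromosome 11, the liver-only region at 68985905 to 68986064 (59 and 21) stood beside the kidney-only region at 68985629 to 68985867 (16 and 18). On chromosome 4, 151129251 to 151129411 (19 and 26 in liver) stood beside 151129072 to 151129223 (33 and 37 in kidney). Of the 33 liver-only regions with a mean position up to 1000, 19 (57.6%, 95% Wilson interval 40.8 to 72.8%) had a kidney BMAL1 centre within 500 bp, against 7.44% of all liver-only regions. Of the 104 such kidney-only regions, 20 (19.2%, 12.8 to 27.8%) had a liver BMAL1 centre that near, against 6.05% of all. For mean positions after 1000 and up to 5000, the shares were 16.2% of liver-only and 16.8% of kidney-only regions.

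**Figure D4:**
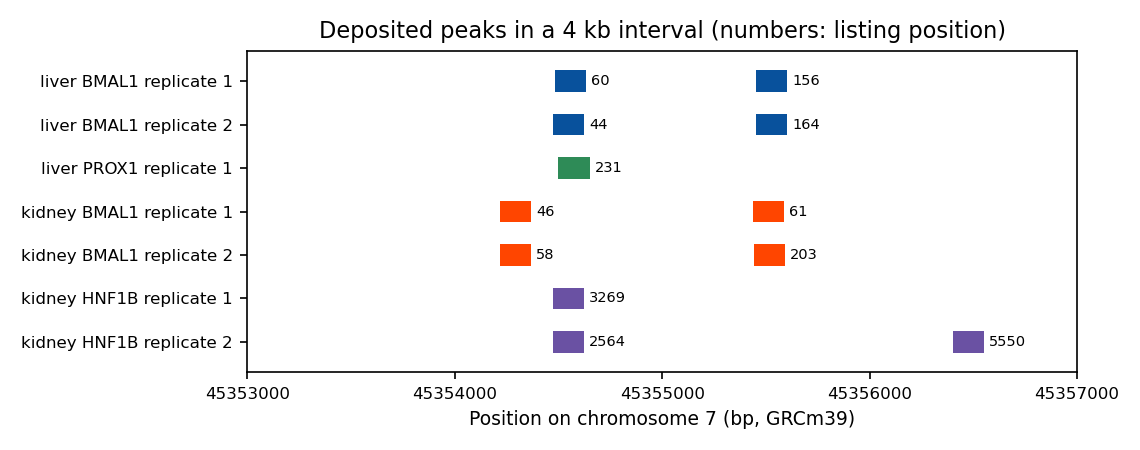
Deposited peaks of the 7 libraries in an interval of chromosome 7 (bp, GRCm39), 1 row per library, with the listing position beside each peak. The liver BMAL1 peaks at positions 60 and 44 and the kidney BMAL1 peaks at 46 and 58 do not overlap, while a BMAL1 region at 45355437 to 45355602 is common to all 4 BMAL1 libraries and has no PROX1 or HNF1B peak.

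Few BMAL1 regions of both tissues lacked both cofactors. Of the 24875 shared regions, 665 had no PROX1 and no HNF1B peak in any library. Those listed first included chromosome 7, 109660790 to 109660954 (positions 67 and 18 in liver, 235 and 71 in kidney), chromosome 3, 138148493 to 138148662 (207 and 145, 63 and 82) and chromosome 7, 45355437 to 45355602 (156 and 164, 61 and 203). A cofactor peak was nevertheless near many of these regions: 226 of the 665 (34.0%, 95% Wilson interval 30.5 to 37.7%) had a PROX1 or HNF1B centre within 500 bp. This held for 9 of the 10 that were among the first 1000 peaks of all 4 BMAL1 lists. The region at 45355437 was an exception, with its nearest PROX1 centre at 945 bp and its nearest HNF1B centre at 957 bp.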

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

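The log2 odds ratios of each tissue were fixed before the data were examined, and the test of their difference, its values under other settings and those in strata were chosen after the main results had been seen. At tissue-only against shared BMAL1 regions, the log2 odds ratio of a cofactor peak was -1.04 for PROX1 in liver and -1.26 for HNF1B in kidney. The difference was -0.22 ± 0.061, and its 95% interval excluded 0. The SE is from a jackknife over chromosomes, since both odds ratios use the same 24875 shared regions. The sign of this difference went with the tissue from which a BMAL1 library was left out, so that 1 library sufficed there. It was 0.63 without liver BMAL1 replicate 1 and 0.59 without replicate 2, against -0.69 without kidney BMAL1 replicate 1 and -0.75 without replicate 2. With 1 HNF1B library alone it was -0.25 (replicate 1) and -0.17 (replicate 2). It was also above 0 with centres within 500 bp (0.06), with a peak in either replicate (0.04) and without regions in all 7 libraries (0.18). Within 4 strata of listing position the pooled difference was 0.03 ± 0.052, but the strata went opposite ways. The SE of this pooled value treats regions as independent and ignores that the tissues have the shared regions in common. In the first 3 strata the log2 odds ratio was lower in kidney (-0.76, -0.68 and -0.62) than in liver (0.10, -0.53 and -0.60), and in the last it was higher in kidney (-0.41) than in liver (-0.81). The differences within single strata were not tested. No direction of the tissue difference therefore held across the settings run, and antibody, tissue and collection time differ together in it.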

How the results depend on the processing

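Settings chosen after the data were seen were centres within 500 bp, the first 5000, 10000, 20000 and 60000 peaks, sequence choice and strata of listing position. The cofactor contrasts with the other tissue's BMAL1 regions kept their direction and passed the test under every setting run. Those with shared regions did so except without regions in all 7 libraries, where they reversed to 1.92 (PROX1) and 2.10 (HNF1B); this exclusion, added afterwards for these contrasts, removes only shared regions that have the cofactor. With 1 replicate left out, they ranged from 4.15 to 6.74 and from -1.70 to -0.88 for PROX1 (against the other tissue, and against shared regions), and from 4.02 to 5.94 and -1.68 to -1.07 for HNF1B. The co-occurrence log2 odds ratio reversed to -1.23 with either replicate, where a peak in 1 replicate no longer counted as absence. It reversed to -1.001 without regions in all 7 libraries, which changes the background and removes only co-occurring regions. It ranged from 0.31 to 0.60 with 1 library left out and was 1.91 for the first 10000 peaks. With a replicate block it was -0.0705, and the block turned no other contrast but the difference between tissues of the contrasts with shared regions (kidney minus liver, -0.22), to 0.0565. That difference reversed also to 0.0637 with centres within 500 bp, 0.0375 with either replicate, 0.18 without regions in all 7 libraries and 0.0277 within strata of listing position, and ranged from -0.75 to 0.63 with 1 replicate left out. The mean Jaccard index of same-numbered minus other libraries was -0.000618 for kidney BMAL1 with HNF1B, 0.000454 for BMAL1 across tissues and 0.00277 for liver BMAL1 with HNF1B. The labels tie no number to an animal or day, so the numbers were not taken to pair the samples. The percent of liver and of kidney BMAL1 regions that were shared was 47.7 and 38.5 with centres within 100 bp, 53.2 and 44.6 within 500 bp, 55.9 and 44.97 for the first 10000 peaks, 46.5 and 43.0 for the first 60000, 45.3 and 42.6 with either replicate, and 18.7 and 13.9 without regions in all 7 libraries. With 1 replicate left out it ranged from 39.5 to 53.7 and from 34.7 to 48.7. The first 10000 peaks gave 3769 shared, 2429 liver-only and 3513 kidney-only regions, and either replicate 39502, 47681 and 53314. Without regions in all 7 libraries, 5952 shared regions remained. These changes in number follow from fewer or more peaks entering. For the first 10000 peaks, HNF1B was present at 41.0% of kidney-only and 3.66% of liver-only regions. PROX1 was then present at 61.8% of liver-only and 6.49% of kidney-only regions. With 1 replicate left out the numbers were 26498 to 30089 shared, 23495 to 39373 liver-only (highest without liver BMAL1 replicate 1) and 31750 to 42348 kidney-only. Replicate overlap in percent for liver BMAL1, kidney BMAL1 and HNF1B was 68.8, 76.8 and 79.0 with centres within 100 bp, 78.6, 83.1 and 85.03 within 500 bp, and 67.1, 83.7 and 86.0 for the first 10000 peaks. The excess of the Jaccard index across tissues over that with the cofactor, positive for the first 1000 peaks, reversed in liver to -0.0306 (first 5000), -0.233 (first 20000) and -0.290 (all). In kidney it was 0.0707 for the first 5000 and reversed to -0.165 and -0.285. With 1 replicate left out it was 0.0981 to 0.154 in liver and 0.188 to 0.210 in kidney. The cause was not tested except where named. Intended settings for promoter distance, motifs, annotation, gene lists and peak score, fixed beforehand, were not run. Depth per peak was not used here.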

Other observations

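The test of clustering in intervals and the comparison of listing order between BMAL1 and its cofactors were written down before their results were seen, and all other tests in this part were chosen afterwards. Tissue-only BMAL1 regions were crowded in particular stretches of the genome. The stretches named here were picked for a large difference between the numbers of liver-only and kidney-only regions. In intervals of 200 kb, chromosome 4, 60600001 to 60800000, held 19 liver-only regions and 1 kidney-only region, and 14 of the liver-only regions had a PROX1 peak. Chromosome 1, 136800001 to 137000000, held 16 liver-only regions and 0 kidney-only regions. In kidney, chromosome 7, 117000001 to 117200000, held 22 kidney-only regions, 16 of them with HNF1B, and 1 liver-only region, and chromosome 10, 85800001 to 86000000, held 18 and 0. Intervals with at least 10 tissue-only regions numbered 190 for liver, against 45 to 74 in 100 permutations of the classes within chromosomes, and 411 for kidney, against 252 to 323. The smaller of the observed numbers relative to the highest permuted one was 1.27. Tissue-only BMAL1 regions thus lay together more than merged regions drawn at random within the same chromosomes. Crowding of shared or other regions was not counted, and why tissue-only regions lay together was not tested.

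Of the regions among the first 1000 peaks of both lists, 77.5% (95% Wilson interval 74.3 to 80.3%) of 732 for kidney BMAL1 and 75.2% (72.2 to 78.0%) of 848 for HNF1B had a PROX1 peak in liver. For the first 5000 peaks the shares were 73.0% (71.6 to 74.3%) of 4002 and 67.0% (65.6 to 68.4%) of 4258. The difference was not tested, and the sets have regions in common. HNF1B regions without a peak in any of the other 5 libraries numbered 7791, and PROX1 regions without a peak in the other 6 numbered 6902. Those listed first included chromosome 6, 47734613 to 47734765 (positions 19 and 52 in HNF1B), and chromosome 15, 81695258 to 81695408 (382 in PROX1), which lay 261 bp and 173 bp from a liver BMAL1 centre. Liver-only and kidney-only regions were spread differently over 7 of 21 chromosomes after Benjamini-Hochberg adjustment (Fisher's exact test): chromosome 6 held 6.50% of liver-only and 5.44% of kidney-only regions (adjusted p = 3.31e-06), and chromosome 14 held 3.93% and 4.91% (adjusted p = 9.12e-07). This test counts every region as independent although tissue-only regions were crowded, so these p-values can be too small. Chromosome Y peaks made up 0.171 ± 0.029% of peaks in the 4 kidney libraries and 0.0645 ± 0.015% in the 3 liver libraries (SD; exact permutation test, two-sided, p = 0.0571, the smallest that the 35 splits can give with both tails counted). This test takes libraries of different antibodies as exchangeable, and the labels do not show that they came from separate animals.

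Whole BMAL1 lists paired with the cofactor of their tissue and first-listed BMAL1 peaks with BMAL1 of the other tissue. Unequal list lengths are argued against, since with 60000 peaks per list the lowest index of BMAL1 with its cofactor still exceeded the highest across tissues by 0.274. With regions in all 7 libraries kept, HNF1B was less frequent at kidney-only than at shared sites. Its log2 odds ratios were -0.58 over 4 strata of listing position and -0.76 in the foremost. For PROX1 the value over all strata was -0.61, but that in the foremost, 0.10, did not pass the test. Without regions in all 7 libraries, and without strata, the values were 2.10 (HNF1B) and 1.92 (PROX1), an exclusion of only shared regions with the cofactor. Neither set of values decides on a preference for tissue-only sites, since any antibody may give a peak at regions in all 7 libraries. Enrichment of accessible chromatin by any antibody, with no input to remove it, may underlie the overlap with cofactors and cannot be told apart from joint binding: the lowest rank correlation of listing position with the cofactor minus that between replicates was -0.202, in kidney (0.728 against 0.929), between the bounds set for either reading. Even PROX1 with HNF1B, which share neither antibody nor tissue, correlated at 0.588 to 0.596, far above the bound set against such enrichment. The test could therefore hardly have argued against it. In liver, PROX1 correlated at 0.881 with BMAL1 replicate 1, within the bound set for such enrichment, and at 0.797 with replicate 2, outside it, against 0.863 between the replicates, and tissue, antibody and time remain open as biological sources.

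Some first-listed tissue-only regions lay beside a BMAL1 peak of the other tissue: the share within 500 bp was 57.6% of 33 liver-only and 19.2% of 104 kidney-only regions of mean position up to 1000. For mean positions after 1000 and up to 5000 the shares were 16.2% and 16.8%, so only the liver-only share stood apart at the front. Such neighbours may be 1 bound site whose peak centres were placed apart, which cannot be told apart from different bound positions in the 2 tissues, since the share is the observation itself and no other value decides. As the cause of the tissue-only classes as a whole, sites split within 500 bp are argued against. Only 7.44% of all liver-only and 6.05% of all kidney-only regions had a BMAL1 centre of the other tissue that near. With centres within 500 bp joined, the number of tissue-only regions was accordingly 93.7% of the main number. Sites split more widely were not examined.

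Of the 21 regions among the first 50 peaks of all 4 BMAL1 lists, 11 (52.4%) were also among the first 50 of the PROX1 and both HNF1B lists. None of the 11 stood later than position 23 in any list, and 7 lay on chromosome 9 between 3000474 and 3024578. Signal that does not depend on the antibody may account for these 11, which stood far forward in the lists of every antibody and both tissues. No input library was used, so such signal cannot be told apart from binding there. The other 10 were first-listed for BMAL1 without being so for every other list. They do not bear on the 11, and they leave the share over the 21 as a set undecided.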
